A study of Macaca mulatta with 12 samples.

How the data were processed

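The samples were total RNA from single layers of the lateral geniculate nucleus of monocularly deprived rhesus macaques, 1 array per layer and hemisphere. Each of the 6 layers was sampled ipsilateral and contralateral, which gave 12 arrays. Per the labels, layers 2, 3 and 5 on the ipsilateral side and layers 1, 4 and 6 on the contralateral side were deprived, which gave 6 deprived and 6 non-deprived samples. Layers 1 and 2 were taken as magnocellular (4 samples) and layers 3 to 6 as parvocellular (8 samples). The number of animals and which samples shared one were not given in the sources used here. The spread is therefore between layers and hemispheres and may be partly technical. Where samples shared an animal, p-values over layers are too small as statements about animals.

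The deposited table held 1 intensity per probe set and array, positive and on a linear scale, for 22283 probe sets of a human Affymetrix expression array. Macaque RNA on human probes can bind less well where the sequences differ, so levels were compared between arrays within a probe set, and means of different probe sets served only to filter and to keep 1 per gene. The software that made the deposited intensities, and any detection calls, were not given in the sources used here. The 2%-trimmed means of the 12 arrays lay between 1500.45 and 1500.6, a largest difference of 0.01%, so the table had been scaled between arrays before it was deposited. By a rule set before the data were examined (trimmed means within 5%), it was used as deposited. Of the probe sets other than 68 controls, 19065 named 1 gene, 1043 named several and 2107 had no gene named here, and no gene was named from a probe set with several. Of 11963 gene symbols, 11290 (94.4%) were also in the macaque gene tables. No genome build was named, so no coordinates are given.

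Values below the pooled 20th percentile (110.8) were raised to it, which affected 0.068% of the values of the probe sets tested, and log2 was taken. Probe sets whose mean log2 value was at or above the median over all probe sets were tested, controls left out, which left 11105. The tests used lmFit and eBayes with a trend in limma 3.58.1 under R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of adjusted p under 0.05. The fit held deprivation, cell class and hemisphere as additive terms over all 12 arrays and left 8 residual degrees of freedom. The eye of input and the interaction of deprivation with cell class were each added to that fit, which left 7. The eye-of-input term is the same contrast as the interaction of deprivation with hemisphere, and the design does not separate these. The difference in deprivation effect between hemispheres is 2 times the eye term, which is the value given here. Unless stated otherwise, a change is a log2 difference with its standard error, a level is a mean scaled intensity with its SD over samples, and an adjusted p is from limma.

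From general knowledge, 24 gene lists were fixed before the data were examined. For lists, 1 probe set per gene was kept, that of the highest mean, which gave 7285 genes. The 22 lists with at least 3 measured genes were tested with camera at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment, and again with an estimated correlation. Members past the threshold were counted over all probe sets and adjusted over the list alone. The list of reported magnocellular markers was recalled from earlier macaque work, and whether that work used these samples is not known, so its direction is not independent evidence. A list score is the mean over members of log2 intensity minus the member's own mean over the arrays.

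The rule for named genes was fixed before the data were examined. It took, among probe sets past the threshold that named 1 gene, the 10 largest changes in each direction that had the same sign in at least 5 of 6 layers (deprivation, hemisphere) or in both hemispheres (cell class, eye), with 5 per direction for hemisphere, eye and interaction. Where fewer than 5 passed in a direction, the genes of the 5 smallest p are given as not passing. It added the 2 members of smallest p in each list, members past the threshold over the list alone, and 18 fixed genes. Among the fixed genes that lay below the filter or were not measured were FOS, BDNF and FOXP2. Genes named beyond this rule are said to be chosen after their values were seen.

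The fit was tested on 10 simulated sets of 12 arrays with the real spread, class and hemisphere effects and 200 changed probe sets among 11105. For the deprivation comparison it called 64.6% of log2 changes of 1, 89.2% of 1.5, 98.6% of 2 and 99.8% of 3, and 5.36% of calls fell on unchanged probe sets. Of 50 simulated lists of 20 genes among 7285, camera called 100% when shifted by 0.25 and 2% when not shifted, with independent noise between genes. The alternatives were the layer number as a block, no hemisphere term, no cell class term, quantile normalization, median centring, no floor, a pseudocount, no filter, a filter at the 75th percentile, eBayes without a trend, subsets of layers, fry, the mean of a gene's probe sets, and leaving out each array. As added alternatives chosen after seeing the data, the 3'/5' ratios of the GAPDH and ACTB control probe sets were used as covariates, and the 2 arrays of highest GAPDH ratio were left out. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.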

Results

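Gene expression was measured by array in the 6 layers of the lateral geniculate nucleus, the thalamic relay between the retina and the visual cortex, of rhesus macaques in which 1 eye had been deprived. Each layer receives input from a single eye, so every layer was sampled once as a deprived layer in 1 hemisphere and once as a non-deprived layer in the other, for 12 arrays in all. The arrays had equal trimmed means, but their median intensity ranged from 411.5 to 666.5. It was higher ipsilaterally (586 ± 83.4, SD, n = 6) than contralaterally (468 ± 39.7, n = 6; two-sided exact permutation p = 0.0195, 1 of 12 such comparisons of array measures). The deprived ipsilateral layer 2 stood apart, with a mean correlation of 0.868 with the other arrays against 0.897 to 0.934. The 3'/5' intensity ratio of the GAPDH control, which rises as RNA degrades, was 9.38 on that array and 11 on the deprived ipsilateral layer 5, and 2.21 to 5.65 on the others. The number of arrays limits the precision of every value.

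The first comparison asked which transcripts differed between layers driven by the deprived and by the open eye. HRK, a pro-apoptotic BCL2-family gene, rose 3.72-fold in deprived layers (log2 change 1.89 ± 0.25, adjusted p = 0.00859), from 970.6 ± 516.7 to 3613 ± 1777 (SD, n = 6 each, limma). PIK3R1, a regulatory subunit of phosphoinositide 3-kinase, rose 3.12-fold, and BRINP3 rose 2.61-fold. KLF4, a zinc-finger transcription factor, rose 2.05-fold from 961.4 ± 207.1 to 1989 ± 512.4, and ADAMTS3, a secreted metalloprotease, rose 1.98-fold. PCGF1, a Polycomb group protein, fell from 2120 ± 322.9 to 645.7 ± 347.8 (log2 change -1.88 ± 0.30), and NQO2, a quinone reductase, fell from 14050 ± 7532 to 5643 ± 1504 (-1.18 ± 0.20).

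Each of these 7 genes moved the same way in 6 of 6 layers, with adjusted p from 0.00859 to 0.0403 by limma. They were the 5 higher and 2 lower probe sets past the threshold of 11105 tested, and 1332 had an unadjusted p under 0.05 where 555.2 would be expected by chance. A second probe set of PIK3R1 (0.50, adjusted p = 0.296) and of PCGF1 (-0.69, adjusted p = 0.142) had the same sign and did not pass. Among genes that did not pass, CRH, the corticotropin-releasing hormone, had a change of -0.99 ± 0.18 (adjusted p = 0.062, 6 of 6 layers; its other probe set -0.87), RITA1 -1.55 ± 0.30 (5 of 6; its other probe set -0.11) and CNNM1 -0.73 ± 0.15 (6 of 6). The count was 0 after median centring or without the cell class term, and 1 without the filter, without a trend or with the GAPDH ratio as a covariate. It was 2 with quantile normalization, 3 with the layer number as a block or without the 2 arrays of highest GAPDH ratio, and 4 in parvocellular layers alone. It was 0 to 3 without any of 9 single arrays (0 without the deprived layer 6), 20 without the deprived layer 5 and 43 without the non-deprived layer 6. Which samples shared an animal was not given, and where some did, these p-values are too small as statements about animals.

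**Figure D1:**
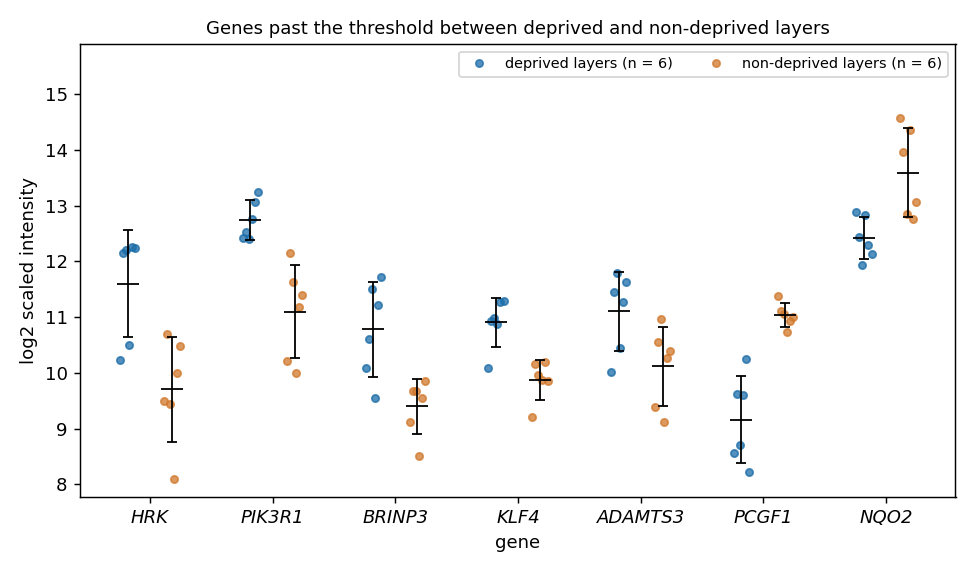
The 7 genes past the threshold between deprived and non-deprived layers. The vertical axis is log2 scaled intensity, each point is 1 array (6 deprived, 6 non-deprived), and the bars are the mean and SD of the log2 values. HRK, PIK3R1, BRINP3, KLF4 and ADAMTS3 were higher in deprived layers, and PCGF1 and NQO2 were lower.

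Genes of energy metabolism were lower together in deprived layers. Nuclear-encoded oxidative phosphorylation genes, which build the respiratory chain, fell as a list (mean log2 change -0.268, 56 of 64 measured members negative, camera adjusted p = 5.96e-14, adjusted p = 0.0217 with an estimated correlation). None of the members passed over all probe sets, and 17 were lower adjusted over the list alone. These were the complex I genes NDUFB7 (-0.80 ± 0.21), NDUFA10 (-0.68 ± 0.17), NDUFA7, NDUFS7, NDUFV2, NDUFB2, NDUFAB1, NDUFS3 and NDUFA2, SDHA of complex II, UQCRC1 of complex III, COX5B of complex IV, and ATP5F1D (-0.66 ± 0.18), ATP5MC1, ATP5PO, ATP5MG and ATP5F1B of ATP synthase. Of the fixed cytochrome oxidase genes, COX6C had a change of 0.03 ± 0.18 and COX7C of -0.22 ± 0.19, and neither passed. Glycolysis genes fell as a list too (mean -0.247, 18 of 20 negative, camera adjusted p = 1.41e-05, adjusted p = 0.0175 with an estimated correlation). Of its members 0 passed over all probe sets and 4 were lower adjusted over the list alone: PKM (-0.77 ± 0.24, its other probe set -0.10), ALDOA (-0.67 ± 0.15), GPI (-0.46 ± 0.14) and GAPDH (-0.45 ± 0.14). As scores of whole arrays, the lists were lower in the deprived sample in 5 of 6 layers, with exact permutation p = 0.013 and 0.0195, and adjusted p = 0.101 for both over the 22 lists. When the signs of the 6 layer differences were flipped instead, the sign-flip p was 0.0625 and 0.125. Each layer difference also holds the hemisphere difference, and both scores were lower ipsilaterally (-0.212 and -0.229). The falls were larger in layers 2, 3 and 5, where the deprived sample was ipsilateral, than in layers 1 and 6. In layer 4 the deprived sample was higher (-0.108 against -0.164, and 0.0603 against -0.0543). With the GAPDH ratio as a covariate the mean changes were -0.262 and -0.233. Markers of oligodendrocytes (mean 0.35), astrocytes (0.212) and endothelium (0.2) passed camera as higher in the same layers (adjusted p = 0.155, 0.174 and 0.132 with an estimated correlation).

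**Figure D2:**
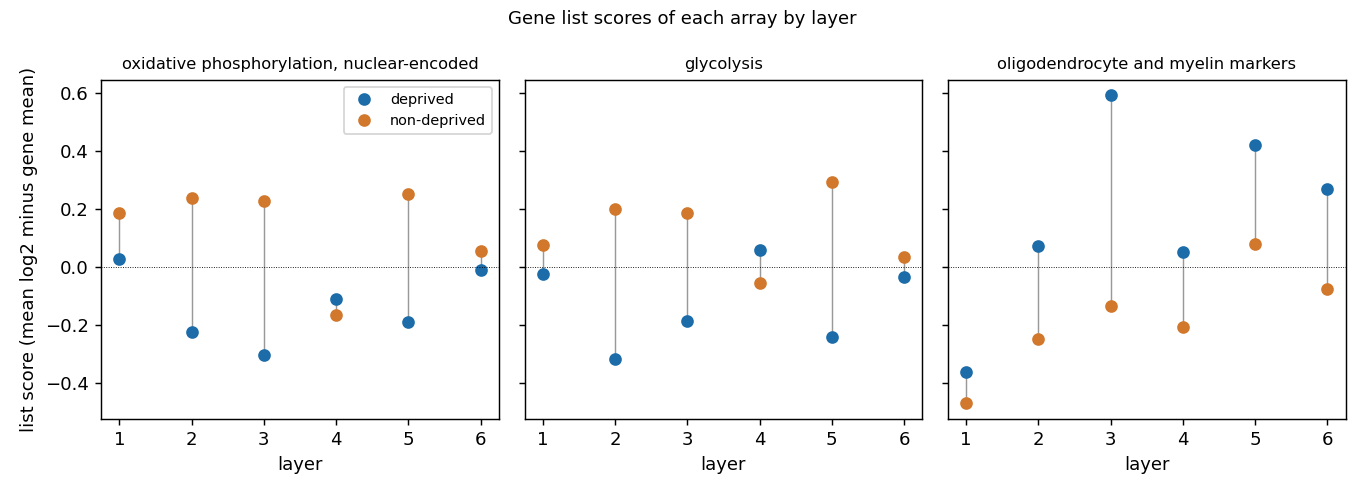
Scores of 3 gene lists by layer. The vertical axis is the mean over list members of log2 intensity minus each member's mean, the horizontal axis is the layer, each point is 1 array, and a line joins the deprived and non-deprived sample of a layer. The oxidative phosphorylation and glycolysis scores were lower in the deprived sample in 5 of 6 layers, and the oligodendrocyte score was higher in 6 of 6.

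Of the 22 lists tested, 11 passed camera with deprivation, 7 lower and 4 higher, and the other 9 lost their call with an estimated correlation. Of the 22, 6 passed with quantile normalization, 6 with fry and 7 without the non-deprived layer 6. Proteasome genes were lower (mean -0.212, 24 of 28 negative; PSMB3 -0.63 ± 0.20, PSMA7 -0.45 ± 0.18), with adjusted p = 0.142 with an estimated correlation and 0 members lower adjusted over the list alone. Their mean was -0.131 without the 2 arrays of highest GAPDH ratio. Genes of the neuronal cytoskeleton were lower as a list (mean -0.132, 25 of 31 negative, adjusted p = 0.113 with an estimated correlation; -0.0635 in parvocellular layers alone). Adjusted over the list alone 4 members were lower, MAP1A (-0.64 ± 0.14, its other probe set of opposite sign), NEFM (-0.53 ± 0.11), STMN2 (-0.35 ± 0.11) and NEFH (-0.35 ± 0.10), and 2 higher, DPYSL3 (0.69 ± 0.19) and STMN4 (0.63 ± 0.20). Reported magnocellular markers, of which NEFM and NEFH are also members, were lower (mean -0.192, 7 of 8 negative, 2 lower adjusted over the list alone, adjusted p = 0.132 with an estimated correlation), a list that is not independent evidence of its direction. Synaptic vesicle and release genes were lower (mean -0.172, 27 of 33 negative, adjusted p = 0.142 with an estimated correlation), with 1 lower adjusted over the list alone, VAMP1 (-0.64 ± 0.13), while SYPL1 had a change of 0.66 ± 0.20. The mean of this list was -0.0972 without the deprived layer 2, the array that stood apart, and in parvocellular layers alone it did not pass (-0.0458, camera adjusted p = 0.098). Heat shock and chaperone genes were lower (mean -0.162, 19 of 23 negative, adjusted p = 0.174 with an estimated correlation), with 1 lower adjusted over the list alone, BAG3 (-0.60 ± 0.16), and CCT7 at -0.35 ± 0.18. This list did not pass without the non-deprived layer 6 (-0.107, camera adjusted p = 0.135) or without the 2 arrays of highest GAPDH ratio (-0.0991, camera adjusted p = 0.142). The heat shock call held in 12 of 17 other settings, and its score changed by -0.118 ± 0.0604 with the GAPDH ratio as a covariate. With quantile normalization the cytoskeleton (-0.0573), magnocellular (-0.131), synaptic (-0.146) and heat shock lists (-0.137) did not pass (camera adjusted p from 0.0665 to 0.231). No member of these 5 lists passed over all probe sets.

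Oligodendrocyte and myelin markers passed camera as higher in deprived layers (mean 0.35, 17 of 18 positive, adjusted p = 0.155 with an estimated correlation). Of its members 0 passed over all probe sets and 5 were higher adjusted over the list alone: EVI2A (0.78 ± 0.21), QKI (0.71 ± 0.18), CNP (0.67 ± 0.20), FA2H (0.59 ± 0.19) and TF (0.57 ± 0.20). MBP, myelin basic protein, had a change of 0.08 ± 0.13. Astrocyte markers passed as higher (mean 0.212, 15 of 19 positive, adjusted p = 0.174 with an estimated correlation), with GFAP at 0.62 ± 0.19 and AGT at 0.49 ± 0.17. Endothelial and mural markers passed as higher (mean 0.2, 16 of 20 positive, adjusted p = 0.132 with an estimated correlation), with ACTA2 at 0.53 ± 0.23 and CAV1 at 0.44 ± 0.20. Markers of koniocellular layers, which also hold relay neurons, passed as higher (mean 0.384, 5 of 5 positive, adjusted p = 0.132 with an estimated correlation), with GRB14 at 0.62 ± 0.22, CAMK2N1 at 0.30 ± 0.14, CAMK2A at 0.35 ± 0.28 and CALB1 at 0.36 ± 0.27. No member of these 3 lists passed over all probe sets or adjusted over the list alone. The endothelial call did not hold without the deprived layers 2 or 3 or the non-deprived layers 2, 4 or 6 (0.162 to 0.215, camera adjusted p up to 0.105), and held in 10 of 17 other settings. The astrocyte call did not hold without the deprived layers 1 or 3 or the non-deprived layers 2 or 6 (0.145 to 0.194, camera adjusted p up to 0.11), and held in 14 of 17. The koniocellular call did not hold without the deprived layer 3 or the non-deprived layer 6 (0.313 and 0.323, camera adjusted p up to 0.0676). Microglia markers did not pass (mean 0.183, camera adjusted p = 0.0964; CX3CR1 0.47 ± 0.19, CTSS 0.34 ± 0.23). They passed without the deprived layers 1 (0.233) or 4 (0.243, camera adjusted p = 0.0271) and with the mean of a gene's probe sets (0.225), and had 0.0784 without the non-deprived layer 6. Of 2 measured blood genes, too few to test, HBB had a change of 0.34 ± 0.27 and HBD of 0.13 ± 0.27.

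The remaining lists did not pass with deprivation. Thalamic relay neuron markers had a mean change of -0.0869 (camera adjusted p = 0.394; CACNA1G -0.52 ± 0.19, RORA -0.29 ± 0.22), and TCF7L2, the only measured parvocellular marker, had 0.05 ± 0.11. Activity-regulated genes had a mean of 0.0637 (adjusted p = 0.482), with EGR3 (0.79 ± 0.22) higher adjusted over the list alone, NPTX2 at -0.56 ± 0.24 and EGR1 at 0.20 ± 0.19. Glutamate receptors (mean 0.204, adjusted p = 0.0582) had 2 members higher adjusted over the list alone, GRM7 (1.10 ± 0.25) and GRM3 (0.48 ± 0.15). This list passed without the deprived layer 6 or the non-deprived layers 1, 3 or 4 (0.226 to 0.249, adjusted p down to 0.0206) and in 3 of 17 other settings, and had 0.129 without the non-deprived layer 6. Ion channels (mean -0.0416, adjusted p = 0.596) had 2 lower adjusted over the list alone, CACNG2 (-0.88 ± 0.25) and KCNH2 (-0.84 ± 0.24, its other probe set of opposite sign), with KCNA1 at -0.37 ± 0.24. GABA genes (mean 0.0529, adjusted p = 0.746) included GAD2 (0.42 ± 0.20), GABRA2 (0.48 ± 0.24) and GAD1 (0.32 ± 0.18). Interneuron markers had a mean of 0.00759 and a median of 0.316, while camera pointed down (adjusted p = 0.902), with RELN (0.79 ± 0.17) higher and CRH and PVALB (-0.51 ± 0.16) lower adjusted over the list alone. Calcium and calmodulin genes had a mean of 0.0418 and a median of -0.00755 with camera down (adjusted p = 0.841; RYR2 0.68 ± 0.20). Neurotrophin genes (mean 0.213, adjusted p = 0.105; IGF1 0.62 ± 0.24, NTRK2 0.51 ± 0.18) and ribosomal proteins (mean -0.0237, adjusted p = 0.394; RPL3 -0.44 ± 0.18, RPL8 -0.32 ± 0.15) did not pass. The list called neurotrophin genes here also held other growth factors and receptors, such as IGF1 and FGF1. The ribosomal list passed as lower without the non-deprived layer 4 (-0.0682) and with the ACTB ratio (-0.0704, adjusted p = 0.0399). MHC class I and complement genes (mean -0.0674, adjusted p = 0.841; TAPBP -0.71 ± 0.37, PSMB9 0.34 ± 0.19, B2M -0.09 ± 0.28) did not pass, nor did the neurofilament gene NEFL (-0.26 ± 0.14). Other probe sets had 0.41 for B2M, -0.03 and 0.20 for NEFL and -0.33 to 0.23 for TCF7L2, and none passed. The p-values of this paragraph are camera adjusted p over 22 lists, and no member of these lists passed over all probe sets. Without the deprived layer 2, the array that stood apart, means were 0.131 for neurotrophin, 0.056 for MHC, 0.12 for activity-regulated, -0.0442 for relay and -0.00987 for ion channel genes. Without the 2 arrays of highest GAPDH ratio the neurotrophin mean was 0.0946. After median centring the means of the activity-regulated, GABA, interneuron and calcium lists were negative (-0.0728, -0.0836, -0.129 and -0.0947), and MBP and TCF7L2 were at -0.05 and -0.08.

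The second comparison set the magnocellular layers, whose large cells carry motion and contrast signals, against the parvocellular layers. The largest increases in magnocellular layers were in NDST4, a heparan sulfate-modifying enzyme (5.73-fold, from 377.7 ± 151.8, n = 8, to 2169 ± 917.6, n = 4, limma adjusted p = 0.00146), and TGFBR2, a TGF-beta receptor (4.06-fold). They were followed by CDH6, a cadherin (3.76-fold, from 2436 ± 681.8 to 8864 ± 655.2), WNT5A, a secreted Wnt ligand (3.39-fold), and ETV1, a transcription factor (2.92-fold). CRH (2.60-fold), ABCA5, the MAP kinase phosphatase DUSP6, MREG and RANBP6 also rose. The largest decreases were in MYL2, a myosin light chain (-2.09 ± 0.26, from 1671 ± 694.3 to 391.2 ± 155), CASQ2, a calcium-binding protein of the sarcoplasmic reticulum (-1.88 ± 0.30), and ADCYAP1, the neuropeptide PACAP (-1.83 ± 0.22, from 2863 ± 507.5 to 850.5 ± 383.7). The next were EGFR (-1.71 ± 0.37), EEF2 (-1.70 ± 0.33), HRK (-1.60 ± 0.26), DUSP5 (-1.60 ± 0.31), PRRC2B (-1.52 ± 0.31), the sodium channel subunit SCN3B (-1.50 ± 0.26) and SYK (-1.49 ± 0.20). Among structural genes NEFM, a neurofilament subunit, rose by 0.83 ± 0.12 and DPYSL3 fell by 1.43 on the log2 scale.

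In this comparison 80 probe sets passed, 33 higher and 47 lower in magnocellular layers, of 27 and 37 genes. Each gene just named had the same sign in both hemispheres, with limma adjusted p from 0.000177 for CDH6 to 0.0422 for EGFR. Other probe sets of the same genes did not pass for CDH6 (0.44), ETV1 (0.05, -0.26 and 0.07), CRH (0.89), DUSP6 (0.54), EGFR (-0.50 and -0.26), EEF2 (-0.66) and PRRC2B (-0.31), while that of WNT5A did (1.45). After median centring 31 passed, 17 higher and 14 lower, and the count was 49 with quantile normalization, 24 without the filter, 41 without a trend and 26 without the 2 arrays of highest GAPDH ratio. It was 6 without layers 5 and 6, 2 in non-deprived samples alone, and 17 to 188 without single arrays (17 without the deprived layer 1, 188 without the non-deprived layer 6). The 3'/5' ratio of the ACTB control was higher in magnocellular (46.4 ± 15.1, SD, n = 4) than in parvocellular layers (25.7 ± 8.79, n = 8, exact permutation p = 0.0162). With that ratio as a covariate 4 probe sets passed, of CDH6, WNT5A, ADCYAP1 and SYK.

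**Figure D3:**
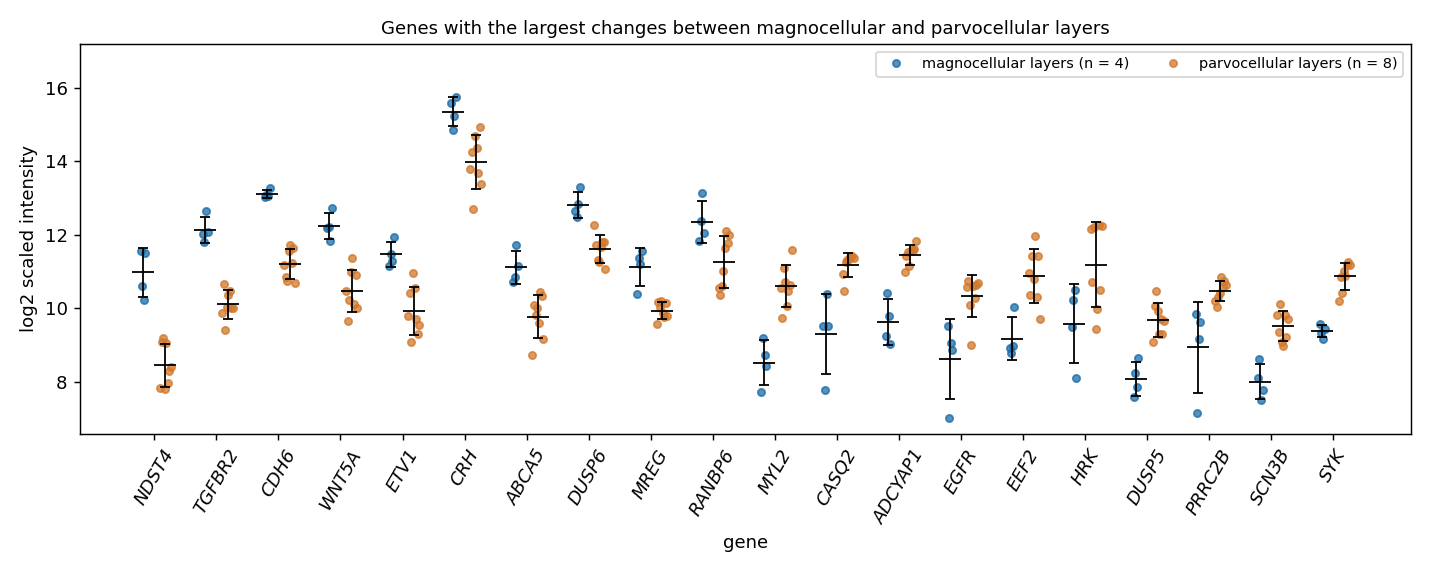
The 10 genes with the largest increase and the 10 with the largest decrease in magnocellular against parvocellular layers. The vertical axis is log2 scaled intensity, each point is 1 array (4 magnocellular, 8 parvocellular), and the bars are the mean and SD of the log2 values. CDH6 and TGFBR2 were higher and ADCYAP1 and SYK lower in magnocellular layers.

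Activity-regulated genes, which neuronal firing induces, fell as a list in magnocellular layers (mean -0.399, 19 of 24 negative, camera adjusted p = 0.0025, adjusted p = 0.372 with an estimated correlation). Over all probe sets 3 members were lower, ADCYAP1, DUSP5 and EGR1 (-1.15 ± 0.20), and 1 was higher, DUSP6 (1.20 ± 0.22). Adjusted over the list alone 8 were lower, which added FOSL2 (-1.45 ± 0.38), EGR3 (-0.81 ± 0.23), JUN (-0.73 ± 0.20), KLF10 (-0.65 ± 0.16) and RGS4 (-0.46 ± 0.18), and 2 were higher, which added RGS2 (0.55 ± 0.19). Oligodendrocyte and myelin markers fell as a list (mean -0.376, 14 of 18 negative, camera adjusted p = 0.000593, adjusted p = 0.372 with an estimated correlation). Of its members, MAG (-1.26 ± 0.23) and MBP (-0.64 ± 0.13) were lower over all probe sets and 8 were lower adjusted over the list alone, the others being CRYAB, FA2H, SOX10, EVI2A, MOBP and ENPP2 (-0.71 to -0.46). With the ACTB ratio as a covariate the mean was -0.101 (camera adjusted p = 0.752), and with the GAPDH ratio it was -0.361. Ribosomal protein genes were lower (mean -0.172, 42 of 51 negative, camera adjusted p = 0.00515, adjusted p = 0.697 with an estimated correlation; RPS27 -0.90 ± 0.27, RPS9 -0.56 ± 0.16), and their mean was 0.108 with the ACTB ratio as a covariate. The ribosomal list did not pass without the deprived layer 1 (-0.115, camera adjusted p = 0.101), without layers 5 and 6 (-0.117) or after median centring (-0.086). In non-deprived samples alone neither it (-0.0619) nor the activity-regulated list (-0.265, camera adjusted p = 0.0602) passed.

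Proteasome genes passed camera as higher in magnocellular layers (mean 0.199, 23 of 28 positive, adjusted p = 0.372 with an estimated correlation), with PSMA4 at 0.78 ± 0.24 and PSMA2 at 0.61 ± 0.17. Heat shock genes passed as higher (mean 0.181, 18 of 23 positive, adjusted p = 0.372 with an estimated correlation), with HSPA5 at 0.85 ± 0.26. They did not pass without the deprived layer 1 (0.141, camera adjusted p = 0.0808) or in non-deprived samples alone (0.182, camera adjusted p = 0.0661). Oxidative phosphorylation genes passed as higher (mean 0.0867, 44 of 64 positive, adjusted p = 0.372 with an estimated correlation), with NDUFV2 at 0.60 ± 0.16, ATP5MC1 at 0.53 ± 0.16, COX6C at -0.19 ± 0.20 and COX7C at 0.06 ± 0.20. They did not pass without the non-deprived layer 1 (0.0436, camera adjusted p = 0.146), and their mean was 0.144 without layers 5 and 6, 0.164 with the ACTB ratio and 0.172 after median centring. None of the members of these 3 lists, 0 of each, passed over all probe sets or adjusted over the list alone. Interneuron markers passed as higher (mean 0.341, median 0.115, 5 of 7 positive, adjusted p = 0.372 with an estimated correlation), with CRH higher over all probe sets and CRH and GAD1 (0.61 ± 0.19) adjusted over the list alone. Without the filter the mean of this list was -0.0733 (camera adjusted p = 0.553). It did not pass without the deprived layer 1 (0.264), in non-deprived samples alone (0.272) or without layers 5 and 6 (0.215, camera adjusted p = 0.0902).

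The other lists did not pass between the classes. Reported magnocellular markers (mean 0.0794, median -0.0313, camera adjusted p = 0.121) had NEFM higher over all probe sets and NEFM, NEFH (0.46 ± 0.11, its other probe set past the threshold at 1.01) and NEFL (0.40 ± 0.14) adjusted over the list alone, and KCNA1 at -0.16 ± 0.25. Neuronal cytoskeleton genes (mean -0.106, camera up, adjusted p = 1) had 3 members higher (NEFM, NEFH, ANK2 at 0.53 ± 0.15) and 2 lower (DPYSL3, STMN4 at -0.82 ± 0.22) adjusted over the list alone. Ion channels (mean -0.0795, adjusted p = 1) had KCND3 higher (0.91 ± 0.19) and SCN3B lower over all probe sets. Astrocyte markers (mean -0.0157, camera up, adjusted p = 0.792) had AGT lower over all probe sets (-1.07 ± 0.18), AGT and MLC1 (-1.31 ± 0.38) lower and SLC1A3 (0.97 ± 0.26) higher adjusted over the list alone, and GFAP at -0.12 ± 0.20. Relay neuron markers (mean -0.123, adjusted p = 0.91) had RORA (-0.85 ± 0.23) lower adjusted over the list alone, SLC17A6 at 0.33 ± 0.14 and TCF7L2 at -0.05 ± 0.11. That TCF7L2 value is of the probe set kept for lists. Its other probe sets had -1.001, -0.9494, -0.1071, -0.05558 and 0.07454, and none passed (smallest limma adjusted p = 0.0639). Calcium genes (mean -0.0421, camera up, adjusted p = 1) had ITPR1 (1.28 ± 0.30) higher adjusted over the list alone and NCALD at -0.64 ± 0.21. For NTRK3 the probe set kept for lists had -0.48 ± 0.16 and did not pass, while 4 of its 5 other probe sets passed as lower.

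Means for the lists with no member past the threshold were 0.0583 for GABA genes (adjusted p = 0.452; GABRB1 -0.47 ± 0.17), -0.162 for synaptic vesicle genes (0.452; STX1A -0.87 ± 0.26, NAPA -0.61 ± 0.21). The means were -0.136 for endothelial markers (0.452; IFITM3 -0.80 ± 0.29, ACTA2 0.77 ± 0.25), -0.269 for koniocellular markers (0.452; CAMK2A -0.68 ± 0.29, CALB1 -0.23 ± 0.28, GRB14 -0.24 ± 0.23). The mean was -0.134 for glutamate receptors (0.664; GRIA3 -0.84 ± 0.33, GRIN1 -0.42 ± 0.20). They were -0.211 for MHC class I and complement genes (adjusted p = 0.282; HLA-E -0.50 ± 0.22, C3 -0.45 ± 0.21, B2M -0.18 ± 0.29) and -0.186 for microglia markers (0.371; LY86 -0.44 ± 0.21, LAPTM5 -0.36 ± 0.20). They were -0.0239 for glycolysis (1, camera up; GPI -0.47 ± 0.15, MPC1 0.47 ± 0.20) and -0.0361 for neurotrophin genes (1, camera up; FGF1 0.46 ± 0.23, NTRK2 0.08 ± 0.19). The other probe sets of FGF1 (-0.39), NTRK2 (-0.44 and -0.68) and GRIA3 (0.06) had the opposite sign and did not pass. Without the deprived layer 2, class means were -0.0492 for synaptic vesicle, -0.0256 for MHC, -0.0593 for relay, -0.0318 for ion channel, -0.0625 for cytoskeleton and -0.159 for neurotrophin genes. The p-values are camera adjusted p over 22 lists. HBB (-0.36 ± 0.29) and HBD (-0.62 ± 0.28) did not pass. Where samples shared animals, which was not given, p-values over layers are too small here too.

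Between hemispheres, CTBP2, a transcriptional corepressor, was 2.43-fold higher ipsilaterally (2204 ± 573.9 against 896.7 ± 224.4, n = 6 each, limma adjusted p = 0.0262), and 11 probe sets were lower. The largest decreases were in SPTLC2 (-1.86 ± 0.34, 5 of 6 layers, with its 2 other probe sets of opposite sign), ENSA (-1.22 ± 0.21), TRO (-1.19 ± 0.16), RAN (-1.16 ± 0.21) and the vacuolar ATPase subunit ATP6V0B (-1.06 ± 0.14), the last 4 in 6 of 6 layers. Of TRO's 2 other probe sets 1 had the opposite sign, those of CTBP2, ENSA and RAN had the same sign, and none of them passed. MMP11 (1.29 ± 0.27), SLC6A4 (1.05 ± 0.22), SLC7A9 (0.92 ± 0.19) and MOSPD3 (0.82 ± 0.17) had limma adjusted p = 0.0683 and did not pass. Of the 22 lists 7 passed camera, with proteasome (-0.347), oxidative phosphorylation (-0.212), heat shock (-0.238), glycolysis (-0.229), ribosomal (-0.0797) and cytoskeleton genes (-0.0788) lower and microglia markers (0.43) higher ipsilaterally. Over all probe sets 1 member each of the proteasome, oxidative phosphorylation and glycolysis lists was lower, and adjusted over the list alone 8, 4 and 5 were, with 3 heat shock and 3 cytoskeleton genes lower and 3 microglia markers higher. Glycolysis held with an estimated correlation (adjusted p = 0.0389), and the other 6 did not (adjusted p = 0.0757, 0.0757, 0.125, 0.654, 0.228 and 0.49 with an estimated correlation, in that order). The ribosomal call did not hold without the deprived layer 6 or the non-deprived layers 4, 5 or 6 (-0.0601 to -0.0352, camera adjusted p up to 0.134). The GAPDH ratio was 6.14 ± 3.37 ipsilaterally and 3.2 ± 0.721 contralaterally (SD, n = 6 each, exact permutation p = 0.0519), and the mean correlation with other arrays 0.906 and 0.928 (exact permutation p = 0.039). With that ratio as a covariate the heat shock list score changed by -0.136 ± 0.0718. The count was 0 with either 3'/5' ratio as a covariate, without the filter or without a trend, 30 after median centring (which moved the median of all log2 changes from 0.07 to -0.25) and 851 without the non-deprived layer 6. Where samples shared animals, p-values over layers are too small.

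No probe set passed between layers served by the ipsilateral and the contralateral eye (limma, 730 with unadjusted p under 0.05, 555.2 expected). The smallest p-values were for CLDN15 (1.30 ± 0.24), EEF2 (0.92 ± 0.22), CDCA4 (0.75 ± 0.19), CDC42EP2 (1.15 ± 0.30) and SPN (0.70 ± 0.18), higher in layers of the ipsilateral eye. In the other direction they were for ATXN1 (-0.99 ± 0.20), ATP1B3 (-0.58 ± 0.12), NAP1L3 (-0.84 ± 0.17), PDCD5 (-0.85 ± 0.18) and GGCT (-0.57 ± 0.12). Of the lists, ribosomal (0.155), oligodendrocyte (0.263) and microglia genes (0.27) were higher and proteasome genes (-0.128) lower in layers of the ipsilateral eye. They had adjusted p = 0.449, 0.264, 0.417 and 0.417 with an estimated correlation and 0 members past the threshold over all probe sets or adjusted over the list alone. Without the non-deprived layer 6 the proteasome (-0.0844, camera adjusted p = 0.16) and microglia lists (0.188) did not pass, and without the non-deprived layer 4 heat shock genes did (-0.107, camera adjusted p = 0.0416). No probe set differed in its deprivation effect between magnocellular and parvocellular layers (limma, 969 with unadjusted p under 0.05), and the smallest adjusted p was 0.259. Those of smallest p were HS2ST1 (1.73 ± 0.37), HSPA13 (1.74 ± 0.40), ACSL1 (1.78 ± 0.42), IFI16 (1.82 ± 0.47) and CTNNA1 (1.39 ± 0.36), with the more positive effect in magnocellular layers. The more negative effects were in SPTBN4 (-2.52 ± 0.46), PTGDS (-2.11 ± 0.39), GLRX3 (-2.83 ± 0.55), MARK4 (-2.45 ± 0.49) and CPNE6 (-2.44 ± 0.48). MHC class I and complement genes passed camera (-0.655, 10 of 10 negative, adjusted p = 0.922 with an estimated correlation). They did not pass without the deprived layer 2 (-0.399, camera adjusted p = 0.168), 1 of the 2 deprived magnocellular arrays and the one with the lowest score (-0.595). Nor did they without the deprived layer 3 or the non-deprived layers 1, 2, 4 or 6 (-0.726 to -0.575, camera adjusted p up to 0.158). Ribosomal genes (-0.22, camera adjusted p = 0.16) passed without the deprived layers 2 or 4 or the non-deprived layers 3 or 5 (-0.324 to -0.265), and synaptic vesicle genes (-0.38) without the deprived layer 1 (-0.543, camera adjusted p = 0.0456). Taken in each class from the same fit, 10 probe sets passed with deprivation in magnocellular layers (2 higher, 8 lower) and 2 in parvocellular layers (2 higher). Without the deprived layer 1, 208 probe sets passed in this comparison, a fit in which the magnocellular deprived arm held a lone sample, the deprived layer 2 that stood apart, assumed to vary like the others. Where samples shared animals, the p-values of both comparisons are too small in the same way.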

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

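The tests of explanations and the counts over other splits in this part were written down only after the results were seen.

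Other splits of the 12 arrays were counted, 100 drawn for each result with the real one included. For deprivation 1 of 100 gave as many probe sets as the real 7 (highest other 1), between cell classes 1 of 100 (80, highest other 1) and between hemispheres 1 of 100 (12, highest other 3). The other splits left the tested term out of the fit, so its real effect stayed in their spread and can lower their counts. The real counts were thus rare among the drawn splits, which does not exclude chance. For the lists it was 1 of 100 with deprivation (11, highest other 10) and 1 of 100 between classes (7, highest other 6). These camera counts led by a margin of a single list, which does not exclude chance either. With an estimated correlation the counts were 2 and 0, and with fry 6 and 1. Between hemispheres 9 of 100 gave as many lists as the real 7 (highest other 9), and for the eye of input 20 of 100 gave as many as the real 4 (highest other 8), so chance was not excluded for these. Every split reaches the 0 probe sets of the eye of input (100 of 100), so that count decides nothing. The highest other, 22, came from the non-deprived group with the ipsilateral layer 5 in place of layer 6. With deprivation in the fit it rests on these 2 arrays, a structure of the samples that was not tested further.

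Oxidative phosphorylation and glycolysis genes were lower in deprived layers, and 2 of 100 splits gave as small a camera p for the first list (-log10 p 14.6, highest other 16.2). Those splits too left deprivation out of the fit, so this does not exclude chance. Over the 22 lists the exact permutation p = 0.013 of this list became adjusted p = 0.101. The mean score of the lists changed by -0.247 ± 0.0391 with the GAPDH ratio in the fit and -0.258 without it. That ratio was 5.51 ± 3.7 in deprived and 3.83 ± 1.3 in non-deprived layers (SD, n = 6 each, exact permutation p = 0.364), so it could move the score little. The lists were picked from this same comparison, and GAPDH, itself lower in deprived layers, is a member of the glycolysis list. This fit therefore does not decide on RNA degradation as the cause. A lower share of relay neurons cannot be told apart: the relay score lay above that of the lists by 0.171 ± 0.0668 (exact permutation p = 0.193), with its own change at -0.0869 over 8 genes, and oligodendrocyte (0.35), astrocyte (0.212) and endothelial markers (0.2) were higher by camera in the same layers (adjusted p = 0.155, 0.174 and 0.132 with an estimated correlation). Deprivation itself and differences between animals stay open, untested.

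The hemispheres differed in 7 lists, a count that other splits reached, and 1 of them held with an estimated correlation. A wrong side label on the ipsilateral layer 6 array cannot be told apart, since probe sets chosen without it put it at -0.0191, near midway (0) from non-deprived (below) to deprived, the state of the contralateral layer 6, with an error of 0.326 over the 11 other arrays. They put it on the contralateral side (-0.353). Of the 11 others, 8 fell on their own side and 11 on their own deprivation side. The ipsilateral layers 3, 4 and 5 also lay near midway for deprivation (0.0078, -0.016 and 0.0102). The ipsilateral layers 1 and 2 also lay on the contralateral side (-0.216 and -0.0576), so lying there is not particular to layer 6, which lay furthest. By correlation of values centred on each probe set's mean, 2 arrays were closer to the other side. These were ipsilateral layer 6 (mean r 0.0654 with contralateral, -0.214 with ipsilateral arrays) and, by less, layer 1 (-0.0672 and -0.116). Without the ipsilateral layer 6 array the counts rose from 12 to 851 between hemispheres, from 7 to 43 with deprivation and from 80 to 188 between classes. The HRK (697.6) and PCGF1 (2121.5) values of that array lay with non-deprived arrays, genes chosen with it in the fit. The signed mean score of the 7 lists was 0.181 ± 0.0512 with the GAPDH ratio in the fit and 0.231 without it. The lists and their signs came from this same comparison, which favours a positive score, so the score does not decide on RNA degradation as the cause. The ratio was 6.14 ipsilaterally against 3.2 (exact permutation p = 0.0519), and the count of probe sets fell to 0 with it in the fit. A difference of side, dissection or animal stays open, untested.

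Oligodendrocyte and myelin markers were lower by camera in magnocellular layers (adjusted p = 0.372 with an estimated correlation, and adjusted exact permutation p = 0.326 for the score). Their score changed by -0.264 ± 0.102 beyond the mean of astrocyte, microglia and endothelial scores (exact permutation p = 0.0384), a mean that itself changed by -0.113 ± 0.077. The list was picked from this comparison and no 3'/5' ratio was in that fit. A lower share of all non-neuronal cells therefore cannot be told apart. With the ACTB ratio in the fit the oligodendrocyte change was -0.101 ± 0.173 against -0.376, and with the GAPDH ratio it was -0.361 ± 0.135. RNA degradation may account for the change by the first ratio and not by the second, so it cannot be told apart. The error of the ACTB fit covers both 0 and most of the change, because the ACTB ratio moves with cell class. Less myelin in these layers stays open, untested.

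Of 460 groups of arrays, 30 had an array far from the others where chance gives about 23 (1 in 20). In non-deprived layers, ipsilateral layer 4 had a median intensity of 637.8, a proteasome score of -0.274, a microglia score of 0.292, PSMA7 at 8338 and CCT7 at 6416, and ipsilateral layer 6 had ATP5F1D at 4496, GAPDH at 54030 and B2M at 8586. NTRK2 was at 1794 in the contralateral layer 2 and at 4924 in the ipsilateral layer 2, and ACTA2 at 1416 in the contralateral layer 1. Among magnocellular layers, the contralateral layer 2 had a glutamate receptor score of -0.448, EEF2 at 1061 and JUN at 2465, the ipsilateral layer 2 had RPS9 at 6172 and HLA-E at 1761, and the ipsilateral layer 1 had FGF1 at 6311. Among parvocellular layers, the ipsilateral layer 3 had NEFL at 29030, GRB14 at 1862, CRYAB at 10610, SLC1A3 at 31650, MBP at 73300, IFITM3 at 3209 and HBB at 13080, the ipsilateral layer 5 had MPC1 at 2009 and LAPTM5 at 4175, and the ipsilateral layer 4 had NTRK3 at 4679. By hemisphere, CTBP2 was at 1093 in the ipsilateral layer 1, and SPTLC2 at 972.6 in the ipsilateral layer 4 and 1566 in the contralateral layer 6.

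By camera, 5 lists passed on the interaction of deprivation with cell class or on the eye term. The deprivation effect differed between magnocellular and parvocellular layers for MHC class I and complement genes (-0.655, adjusted p = 0.922 with an estimated correlation). Ribosomal, proteasome, oligodendrocyte and microglia genes passed on the eye term (0.155, -0.128, 0.263 and 0.27). This term cannot be told apart from a deprivation effect that differs between hemispheres, a difference 2 times as large. The terms had adjusted p = 0.449, 0.417, 0.264 and 0.417 with an estimated correlation, and 20 of 100 splits gave as many lists. Of 23 control probe sets 0 passed (smallest exact permutation p = 0.0455, adjusted p = 0.514), with all 3 of GAPDH, a member of the glycolysis list, lower in deprived layers (-0.64 to -0.30) and 10 of 12 for ribosomal RNA (-0.638 to -0.244).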

How the results depend on the processing

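The fits with a 3'/5' ratio and without the 2 arrays of highest GAPDH ratio were chosen after seeing the data. Oxidative phosphorylation genes stayed lower with deprivation and past the threshold in 17 of 17 other settings (16 by camera, 1 by fry) (-0.405 to -0.218, adjusted p up to 0.0217) and without each of 12 arrays (-0.307 to -0.239), and glycolysis genes likewise (-0.384 to -0.176, adjusted p up to 0.0175; -0.264 to -0.223). The count of 7 probe sets with deprivation became 2 with quantile normalization, 0 after median centring, 1 without the filter, 1 without a trend, 0 without the cell class term, 4 in parvocellular layers alone, 1 with the GAPDH ratio and 3 without the 2 arrays of highest GAPDH ratio. It was 0 to 43 without single arrays: deprived layers 1 and 2 (3 each), 4 (2), 5 (20) and 6 (0), non-deprived layers 1 and 4 (2 each), 2, 3 and 5 (1 each) and 6 (43). The count of 11 lists with deprivation, of 22 tested, became 6 with quantile normalization, 2 with an estimated correlation, 6 with fry and 7 to 12 without single arrays (7 without the non-deprived layer 6). The 80 probe sets between classes became 49 with quantile normalization, 31 after median centring, 24 without the filter, 41 without a trend, 2 in non-deprived samples alone, 6 without layers 5 and 6, 26 without the 2 arrays and 4 with the ACTB ratio. Without single arrays they were 17 to 188: deprived layers 1 (17), 2 (27) and 6 (35), non-deprived layers 2 (19), 3 (38), 5 (51) and 6 (188). The 7 class lists became 3 in non-deprived samples alone, 0 with an estimated correlation, 1 with fry and 4 to 7 without single arrays (4 without the deprived layer 1). The 12 probe sets between hemispheres became 3 with quantile normalization, 30 after median centring and 0 without the filter, without a trend, with the GAPDH ratio, with the ACTB ratio and without the 2 arrays. They were 0 to 851 without single arrays: deprived layers 1 (0), 2 (3), 3 (4), 4, 5 and 6 (2 each), non-deprived layers 3 (2), 4 and 5 (3 each) and 6 (851). For the eye the count of 0 became 1 without the 2 arrays and 0 to 3 without single arrays (3 without the deprived layer 2), and for the interaction 5 without the filter and 0 to 208 without single arrays (208 without the deprived layer 1, 1 without the non-deprived layer 4). Where a left-out array left a lone sample, it was assumed to vary like the others. Median centring moved the median of all log2 changes from 0.03 to -0.11 with deprivation and from 0.07 to -0.25 between hemispheres, so its values are relative to those medians. Subsets held fewer arrays and the looser filter more tests; the cause was not tested for the other settings. Detection calls were not used here, so signal over background is known only by the floor.

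The arrays of a layer were not treated as pairs. As deviations from their deprivation group's mean, 0 of 6 pairs of deprived and non-deprived arrays had r over 0.1, and 0 samples matched best to their own layer. The arrays of a pair came from opposite hemispheres, and the hemisphere difference left in these deviations lowers r. This check therefore cannot exclude pairing. After hemisphere and class were removed, r was 0.123 and 0.115 for layers 4 and 5 and below 0 for the other 4. With the layer as a replicate block the count with deprivation was 3 in place of 7, and the eye of input could not be fitted.

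After median centring, changes with deprivation of reversed sign were activity-regulated genes -0.0728, GABA genes -0.0836, calcium genes -0.0947, interneuron markers -0.129, TCF7L2 -0.084, HBD -0.0066, COX6C -0.11, MBP -0.052. After median centring, changes between classes of reversed sign were calcium genes 0.0436, ion channels 0.00622, glycolysis 0.0618, neurotrophin genes 0.0496, astrocyte markers 0.0701, TCF7L2 0.036. Without the filter, changes with deprivation of reversed sign were GABA genes -0.018, MHC genes 0.0578. Without the filter, changes between classes of reversed sign were relay markers 0.0341, interneuron markers -0.0733, glycolysis 0.0177. With the filter at the 75th percentile, changes with deprivation of reversed sign were GABA genes -0.00328, calcium genes -0.0147. With the filter at the 75th percentile, changes between classes of reversed sign were calcium genes 0.0112, ion channels 0.0345, cytoskeleton genes 0.0109, neurotrophin genes 0.0891. In parvocellular layers alone, changes with deprivation of reversed sign were GABA genes -0.00873, ion channels 0.0116, interneuron markers -0.0382, ribosomal genes 0.0495, MHC genes 0.151, B2M 0.083. With the ACTB ratio, changes with deprivation of reversed sign were interneuron markers -0.0123, COX6C -0.013. With the ACTB ratio, changes between classes of reversed sign were GABA genes -0.102, relay markers 0.0764, ribosomal genes 0.108, neurotrophin genes 0.015, MHC genes 0.131, astrocyte markers 0.073, microglia markers 0.0223, endothelial markers 0.0274, TCF7L2 0.00012, GRB14 0.12, C3 0.19, ENPP2 0.095, IFITM3 0.29, HBB 0.0801, NTRK2 -0.22, COX6C 0.041, KCNA1 0.098, GFAP 0.44, B2M 0.076. With quantile normalization, changes with deprivation of reversed sign were ribosomal genes 0.0632, COX6C -0.019. With quantile normalization, changes between classes of reversed sign were neurotrophin genes 0.0131. With the mean of a gene's probe sets, changes with deprivation of reversed sign were ribosomal genes 0.000432. Without the 2 arrays of highest GAPDH ratio, changes with deprivation of reversed sign were MHC genes 0.0673, TCF7L2 -0.062, COX6C -0.018, B2M 0.35. Without the 2 arrays of highest GAPDH ratio, changes between classes of reversed sign were calcium genes 0.00954, glycolysis 0.00147, astrocyte markers 0.0311, NTRK2 -0.18, COX7C -0.10, GFAP 0.036. In non-deprived samples alone, changes between classes of reversed sign were GABA genes -0.0342, synaptic vesicle genes 0.0279, ion channels 0.000444, glycolysis 0.0236, MHC genes 0.117, astrocyte markers 0.00732, NTRK2 -0.21, COX7C -0.044, B2M 0.087. Without layers 5 and 6, changes between classes of reversed sign were GABA genes -0.0518, TCF7L2 0.032. With the GAPDH ratio, changes between classes of reversed sign were astrocyte markers 0.0523, B2M 0.092. With the GAPDH ratio, changes with deprivation of reversed sign were COX6C -0.0030, B2M 0.16. Without single arrays, signs changed with deprivation for interneuron markers (-0.0965 to 0.0818), ribosomal genes (-0.0682 to 0.0334), MHC genes (-0.143 to 0.056), TCF7L2 (-0.0033 to 0.092), HBD (-0.021 to 0.33), COX6C (-0.088 to 0.15), MBP (-0.011 to 0.16), B2M (-0.24 to 0.16). Without single arrays, signs changed between classes for calcium genes (-0.0822 to 0.0217), glycolysis (-0.0598 to 0.0037), neurotrophin genes (-0.159 to 0.0273), astrocyte markers (-0.0899 to 0.0508), NTRK2 (-0.16 to 0.20), COX7C (-0.078 to 0.16), KCNA1 (-0.33 to 0.021), CALB1 (-0.40 to 0.0104), GFAP (-0.24 to 0.044).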

Other observations

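Of the 7 probe sets past the threshold with deprivation, 4 also passed between cell classes, each with the opposite sign, a pattern picked out after the values were seen. HRK, BRINP3 and ADAMTS3 were higher in deprived layers and lower in magnocellular layers (class changes -1.60, -1.16 and -1.30), and NQO2 was lower in deprived and higher in magnocellular layers (0.99, limma adjusted p = 0.0373). Independent lists of these sizes would share 0.0212 probe sets higher with deprivation and lower by class, and 0.00594 of the other kind, though both comparisons use each probe set's own estimate of spread, which raises such an overlap. CRH was at -0.99 with deprivation, not past the threshold, and rose in magnocellular layers, also with opposite signs.

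The deprivation effect was also taken in each cell class from the interaction fit. Oxidative phosphorylation genes had a mean of -0.311 in magnocellular layers and -0.247 in parvocellular layers, and glycolysis genes -0.311 and -0.216, each past the camera threshold. The magnocellular values rest on 2 deprived arrays, and scores were lower on the deprived layer 2, the array that stood apart (-0.224 and -0.318), than on the deprived layer 1 (0.0289 and -0.0243). Without the deprived layer 2 (-0.271, camera adjusted p = 0.0637) or the non-deprived layer 1 (-0.248, camera adjusted p = 0.148) the magnocellular glycolysis change did not pass. With an estimated correlation the magnocellular changes had adjusted p = 0.267 and the parvocellular ones adjusted p = 0.0323, for both lists. The difference between the classes was not past the threshold for either list, where MHC class I and complement genes were the only list of 22 that was (adjusted p = 0.922 with an estimated correlation).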
